A study of Mus musculus with 6 samples.

How the data were processed

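Gene expression was measured on 6 mouse Illumina bead arrays, one per sample. Bone marrow from C57BL/6 mice was depleted of lineage-marked cells and held overnight in stem cell factor and thrombopoietin, per the labels' protocols. Cells with CD41 and c-kit on their surface, the megakaryocyte progenitors, were then sorted and cultured for 3 days in thrombopoietin. The genotype label gave 3 samples as SRF wild-type and 3 as SRF knockout, and the series design names 3 mice of each kind, with deletion by Cre recombinase under the Pf4 promoter. The labels number the replicates without tying each to an animal, so p-values measure the spread between these samples.

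Per the file headers, the deposited raw table held for each array and probe a raw intensity, the standard error over the beads, the number of beads and a detection p-value. The raw intensity values were on a linear scale, with no value below 0 and no background subtracted as far as the values show. The deposited detection p-value compares each probe with the negative control beads. BeadStudio 3.2 and lumi were named in the submitters' processing notes, without their roles. The authors' processed values were on a log2-like scale with a raised floor (the lowest value was 7.80), and each column had the same sorted values, with a median of 8.22 in every array, as quantile normalization gives. Their transform and background step are not given in the sources used here, and a unit of that scale need not be a doubling at low intensity. Each processed column matched the raw column of its own sample better than any other (correlation across probes of deviations from the probe mean, 0.905 to 0.969 against at most 0.544).

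Computation used R 4.3.3 and limma 3.58.1. The raw intensities were background-corrected by normexp with negative control levels inferred from the detection p-values, offset by 16, quantile normalized and converted to log2 (neqc). An offset of this size shrinks the differences of dim probes. A probe was tested if its detection p was under 0.05 on all 3 arrays of at least 1 group, which kept 9403 of 24611 probes. limma's linear model with eBayes at default settings compared knockout with wild-type, two-sided, with Benjamini-Hochberg adjustment over the tested probes, and an adjusted p under 0.05 counted as a change. A probe not above background on any array of a group has only a bound there. Its fold was computed from the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest value among detected probes, and is given as at least that many fold.

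Probe names came from the platform annotation: 20983 probes had 1 symbol, 1 had several and 3627 had none. Of the symbols, 20967 matched through the Entrez gene number to the gene table of mouse assembly GRCm38.p6, none changed, and 16 were kept as they stood. That table was used for names and for the order of neighbouring genes; the files name no genome build, so no coordinates are given. The tested probes with a symbol numbered 8343, for 6869 genes, of which 1222 had several tested probes. A gene was represented by its probe with the highest mean log2 intensity, and other probes that differed in call are reported.

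The groups, the test, the alternatives, the named genes and 22 gene lists were chosen before the data were examined. The named genes were Srf, up to 12 genes with the largest falls and up to 12 with the largest rises among those that passed with the arrays of both groups apart, and for each list the 3 tested members with the smallest p, whether or not they passed. This gave 69 genes. The lists covered SRF-MRTF target genes, immediate early genes, actin assembly, integrins and focal adhesion, megakaryocyte and platelet receptors, platelet granules, megakaryocyte transcription factors, tubulins and spectrins, mitosis, DNA replication, stem and progenitor genes, p53 targets, heat shock and unfolded protein response, interferon response and sex-linked genes. They also covered markers of erythroid cells, mast cells and basophils, granulocytes, monocytes and macrophages, lymphocytes, and stromal and endothelial cells. The list of mast cell and basophil markers is called the mast cell list or mast cell markers for short. A further list is not reported here. Members were counted by their adjusted p over all probes and adjusted over the list alone. Each list of at least 2 tested members was tested against all other genes with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation. fry tested each list against no change, once for a shift in one direction on balance and once for change in either direction, without comparing it with other genes. These tests used 1 probe per gene, with adjustment over the lists.

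Alternatives were normexp without control levels at offset 50, no background correction, scaling to the 75th percentile, the authors' processed values, no filter, a stricter filter of detection p under 0.01 on all 6 arrays, 1 probe per gene, the replicate number as a block, eBayes with trend and robust settings, array weights, an unmoderated test, and leaving out each array. A slide block was not run because the files name no slide. Models with the mean of the granulocyte or mast cell markers, and a fit without wild-type replicates 2 and 3, were added after seeing the data. These means cover tested members only, 9 for the granulocyte list and 2, Cpa3 and Mcpt8, for the mast cell list.

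The test was tested on simulated data with the arrays' own means and residual spreads over 9403 probes, of which 200 were changed in each of 20 simulations of the knockout against wild-type comparison. It recovered 55.9% of the probes changed by 1 on the log2 scale and 91.3% of those changed by 2, and 4.48% of its calls were false. The simulated noise was independent between probes. A simulated list with a shift of 0.5 gave a camera p of 2.6e-18, and 1 of 100 unshifted lists had a p under 0.05. Between 39.8% and 42.1% of probes were detected per array, and a probe's intensity averaged over a median of 34 to 36 beads. The median relative standard error over beads was 9.53% on knockout replicate 1 and 4.59% to 6.35% on the other arrays. The number of arrays limits the precision.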

Results

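Transcript levels were measured on bead arrays in mouse megakaryocyte progenitors, the bone marrow cells that give rise to platelet-forming megakaryocytes. The progenitors were sorted by CD41 and c-kit and cultured for 3 days in thrombopoietin. They carried either intact Srf (wild-type, 3 arrays) or Srf deleted by Cre recombinase driven by the promoter of Pf4, a platelet granule gene (knockout, 3 arrays). Srf encodes serum response factor, a transcription factor of cytoskeletal and immediate early genes. The arrays detected 9801 to 10364 probes each, and no pair of arrays shared the raw value of more than 1 of the 24611 probes. The single comparison asked which transcripts differed in progenitors without Srf.

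Srf itself was 25.8-fold lower in the knockout (probe ILMN_2769688) and fell by 4.69 on the log2 scale (SE 0.17, limma adjusted p = 5.4e-05). The 3 wild-type arrays lay at log2 12.31, 11.89 and 11.98, and the 3 knockout arrays at 7.35, 7.56 and 7.20. The knockout arrays remained above background on this probe, with detection p of 0.0036, 0.0012 and 0.0036. A second Srf probe (ILMN_1242533) was dim, with detection on 2 wild-type arrays and no knockout array, and was not tested. The labels do not say which part of the gene was deleted, and where the probes lie relative to it is not known here.

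Beside Srf, 8 named genes fell and 2 rose. Of those that fell, Coro1a, Cnn2 and Flna encode actin-binding proteins. Coro1a, a coronin that binds actin filaments in blood cells, went from log2 14.49 ± 0.01 to 12.30 ± 0.18 (SD, n = 3 each), 4.58-fold lower, and its other 2 probes were 6.93-fold and 7.02-fold lower. Cnn2, calponin 2, was 3.83-fold lower (11.46 ± 0.39 to 9.53 ± 0.07), and Flna, which cross-links actin filaments, 2.96-fold lower (12.63 ± 0.28 to 11.06 ± 0.19). Irak2, a kinase of interleukin-1 and Toll-like receptor signalling, was not well above background in any knockout array and was at least 3.36-fold lower. Ptges3l, seen by 2 probes, was likewise not well above background there and at least 3.66-fold lower by its brighter probe, and Dcaf12 at least 1.74-fold lower. Mtmr14, a phosphoinositide phosphatase, was 2.23-fold lower and Snx24, a sorting nexin, 2.24-fold lower, a fall between dim levels (log2 7.40 and 6.24) whose size depended on the background correction. The gene that rose most was Cxcl5, a chemokine that attracts neutrophils, from 7.01 ± 0.26 to 10.23 ± 0.43, 9.32-fold higher. Mpdu1, needed for the use of dolichol-linked mannose in protein glycosylation, was 2.14-fold higher.

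**Figure D1:**
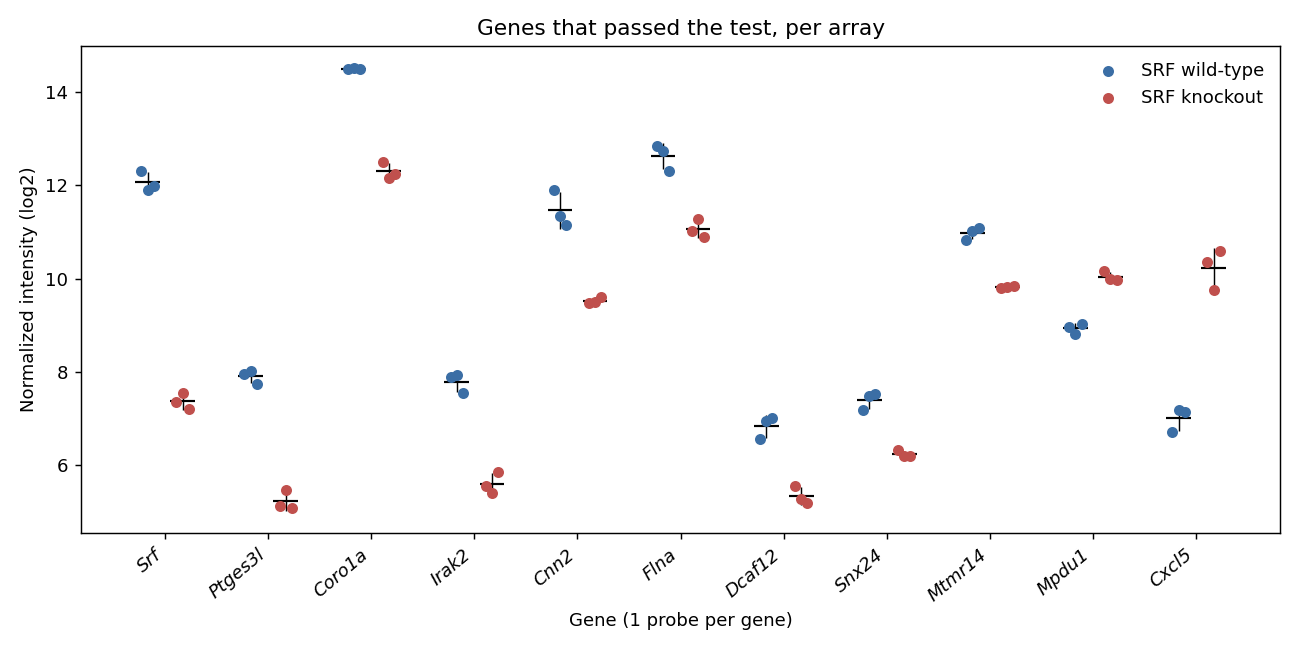
Normalized intensity (log2, vertical axis) of the 11 genes that passed the test, 1 probe per gene, in each wild-type (blue) and knockout (red) array; horizontal bars are means and vertical bars SDs over 3 arrays. Knockout and wild-type arrays are apart for each gene, from Srf (12.06 against 7.37) to Cxcl5 (7.01 against 10.23).

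In all, 15 of 9403 probes changed, 13 lower and 2 higher, which covered these 11 genes and 1 probe without a name. Adjusted p ran from 5.4e-05 for Srf through 9.1e-04 for Coro1a, 0.0023 for Cxcl5, 0.0035 for Irak2, 0.019 for Cnn2 and 0.032 for Flna to 0.037 for Mpdu1 and 0.038 for Snx24. Each of the 15 differed by at least 1 on the log2 scale, with the arrays of the groups apart. Not every probe of a gene passed: a dimmer Cnn2 probe differed by -1.13 (adjusted p = 0.32), and 3 further Mtmr14 probes by -0.77, -0.62 and -0.28. At an unadjusted p under 0.05 there were 1290 probes against 470.2 expected by chance, while the division of wild-type replicate 1 and knockout replicates 2 and 3 against the other 3 arrays, which ignores genotype, gave 1554. Further, 18.9% of tested probes had the groups apart against 10% by chance.

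The count moved with the arrays used: 639 probes changed without wild-type replicate 1 (351 higher, 288 lower), 8 without knockout replicate 1, and 7 without wild-type replicate 2, knockout replicate 2 or knockout replicate 3. In the fits without wild-type replicate 2, wild-type replicate 3, knockout replicate 2 or knockout replicate 3, 1 probe was higher. Srf, Coro1a, Ptges3l, Irak2 and Cxcl5 passed with each array left out, Cnn2 and Flna missed the threshold without wild-type replicate 2 or any 1 knockout array (adjusted p 0.089 to 0.20), and Mtmr14, Dcaf12, Snx24 and Mpdu1 missed it without any 1 array other than wild-type replicate 1 (adjusted p 0.10 to 0.27). Over all alternatives, by 1 probe per gene, Srf passed under 20 of 20, Coro1a under 19 of 20, Cxcl5 and Ptges3l under 18 of 19, Irak2 under 16 of 19, Cnn2 under 14 of 20 and Flna under 12 of 20. Mtmr14 and Mpdu1 passed under 10 of 20, Dcaf12 under 5 of 19 and Snx24 under 4 of 19. Dcaf12 lost its call with normexp at offset 50 (-0.89), without background correction (-0.60) and with percentile scaling (-1.55).

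Among the genes that SRF and its MRTF cofactors are known to activate, 18 of 33 listed members were tested. Cnn2 and Flna fell, none rose and 16 did not pass; adjusted over the list alone, 3 fell. The third was Tpm1, a tropomyosin, at -0.67 (SE 0.15, adjusted p = 0.27 over all probes). Itga5, an integrin subunit, stood at +0.86 (SE 0.26, adjusted p = 0.32). The list's median difference was -0.02, with 10 members lower and 8 higher, and camera did not set it apart from other genes (adjusted p = 0.36, and 0.71 with an estimated correlation), whereas fry's test against no change passed for either direction (adjusted p = 3.1e-04) and not for a shift one way (adjusted p = 0.20). With 1 array left out the median was -0.10 without wild-type replicate 2 or knockout replicate 1, -0.11 without wild-type replicate 3, -0.04 without knockout replicate 2 and +0.03 without knockout replicate 3. Camera did call the list lower in a pair of fits added after seeing the data. They are not separate evidence: the mast cell marker mean was high in wild-type replicates 2 and 3 alone, so both rest mostly on wild-type replicate 1. With that mean in the model the list's median was -0.13 (camera adjusted p = 0.021). Without wild-type replicates 2 and 3 the list's median was -0.14. Over all its alternatives the adjusted p ran from 0.012 to 0.90.

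In the actin assembly list, Coro1a fell and the other 30 of 31 tested members did not pass; adjusted over the list alone, 2 fell. Lima1, which bundles actin filaments, was the second, at -1.86 (SE 0.27, adjusted p = 0.074 over all probes) and detected on 3 wild-type and 2 knockout arrays. Arpc1b, a subunit of the Arp2/3 complex, lay at +0.55 (SE 0.18, adjusted p = 0.32). The median was +0.03 and the mean -0.14, which differ in sign, and the median was -0.05 with no filter and -0.12 with the mast cell marker mean in the model; camera gave an adjusted p of 0.79 and fry's test against no change 3.1e-04 for either direction and 0.32 for a shift one way. Of 20 listed immediate early genes 19 were on the array and 10 were tested. Fos, Fosb, Fosl1, Egr2, Ier2, Ier5, Nr4a1, Btg2 and Atf3 did not pass the detection filter, so the test did not cover them. Of the 10 tested genes none passed over all probes. Adjusted over the list alone Junb rose (+0.90, SE 0.17, adjusted p = 0.20 over all probes), with Egr3 at +0.50 and Jun at -0.40 among the tested genes. The median of the tested immediate early genes was -0.07, or +0.02 without knockout replicate 2, and their mean +0.01 (camera adjusted p = 0.79). Camera called the immediate early list higher in the same pair of added fits, which rest mostly on wild-type replicate 1. The median was +0.07 with the mast cell marker mean (camera adjusted p = 0.034) and +0.19 without wild-type replicates 2 and 3. Over the list's alternatives the adjusted p reached 0.95.

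Genes of the megakaryocyte surface leaned upward together, with no single member past the test over all probes. The receptor and integrin lists both name Itga2b and Itgb3, so they overlap. The estimated inter-gene correlations were 0.43 for receptors, 0.23 for integrins and 0.24 for granule genes. These exceed the preset 0.01, so camera's p-values at the preset value are likely too small. All 20 tested platelet receptor genes were higher in the knockout by mean, with a median of +0.41 (camera adjusted p = 2.2e-06, and adjusted p = 0.60 with an estimated correlation); adjusted over the list alone 1 rose, the thromboxane receptor Tbxa2r (+0.83, SE 0.16). Itga2b, which encodes CD41, lay at 12.55 ± 0.11 in the wild-type and 13.01 ± 0.00 in the knockout (SD, n = 3), and Gp1bb, a subunit of the von Willebrand factor receptor, at +0.77 (SE 0.23). Of 15 integrin and focal adhesion genes 13 were higher, with a median of +0.45 (camera adjusted p = 2.6e-04, and adjusted p = 0.60 with an estimated correlation) and none past the test over all probes or adjusted over the list alone; the members with the smallest p were Itgb2 (+0.54), Itga2b (+0.47) and Itgav, which was not well above background in any wild-type array and at least 1.19-fold higher. Of 22 platelet granule genes 19 were higher, with a median of +0.34 (camera adjusted p = 2.9e-04, and adjusted p = 0.60 with an estimated correlation); adjusted over the list alone 3 rose and 1 fell. Tgfb1 (+0.83, SE 0.21) and F5 (+0.91, SE 0.25) were among those that rose, and Ppbp, the precursor of platelet basic protein, was the one that fell (-0.82, SE 0.17, adjusted p = 0.25 over all probes).

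The receptor, integrin and granule lists depended on wild-type replicates 2 and 3. Granulocyte transcripts were high there (Mpo at log2 14.74 and 14.93, against 7.64 in wild-type replicate 1) and in knockout replicate 1 (13.07). Transcripts of the mast cell and basophil list set wild-type replicates 2 and 3 apart from all other arrays (Cpa3 at 12.64 and 12.88, against 6.62 in wild-type replicate 1 and 7.17 to 8.21 in the knockout). With those 2 arrays left out, a choice made after seeing the data, the medians were +0.22 for the receptors, +0.11 for integrins and +0.06 for granule genes, and camera no longer set the last pair apart (adjusted p = 0.13 and 0.16). The receptors' median was +0.21 without knockout replicate 1. With the mast cell marker mean in the model the medians were +0.26 for receptors, +0.22 for integrins and +0.11 for granule genes, each still past camera's test at the preset correlation, and with no filter the integrins' median was +0.19 over 24 members.

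**Figure D2:**
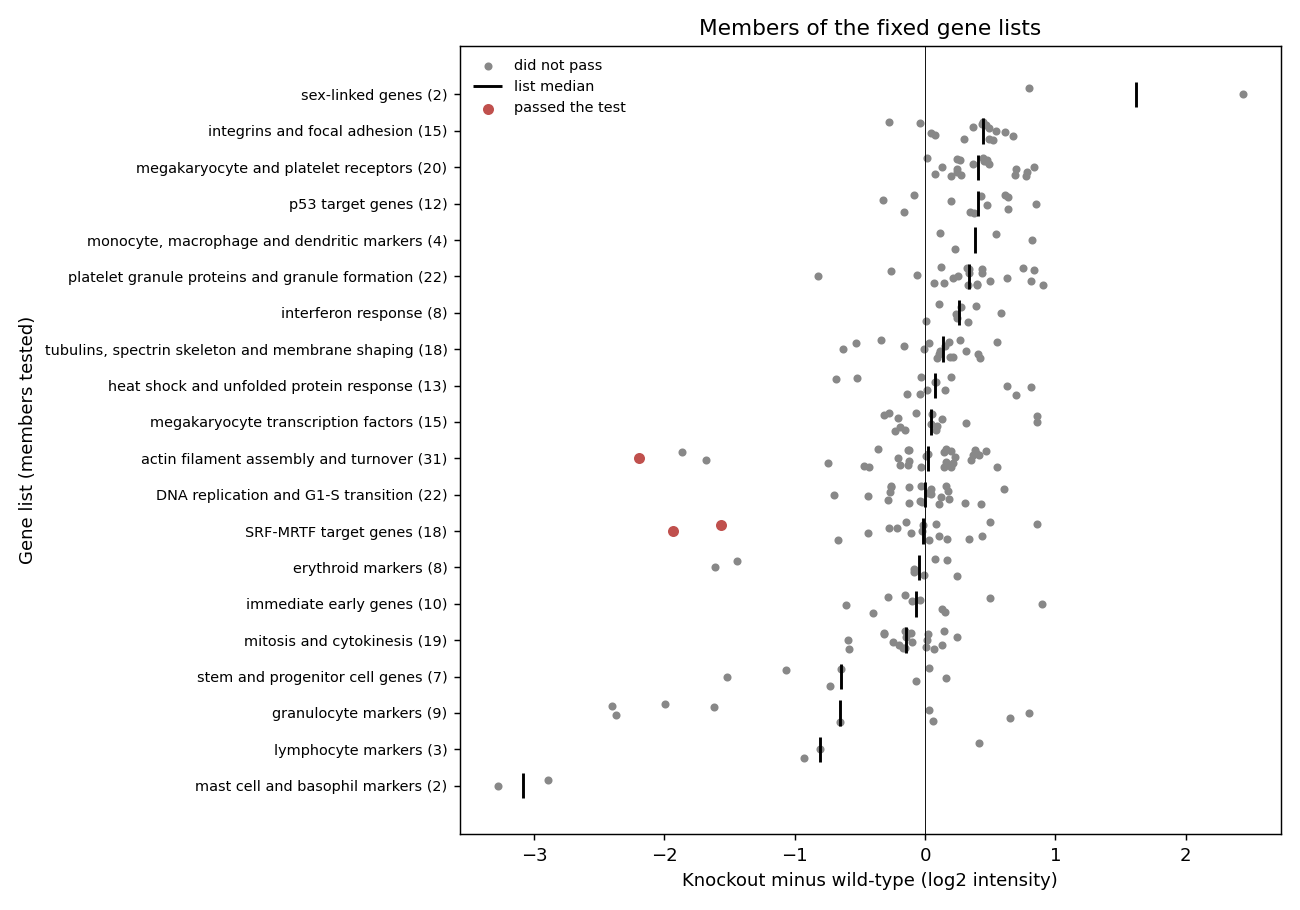
Difference in log2 intensity, knockout minus wild-type (horizontal axis), of every tested member of 20 gene lists (vertical axis, members tested in brackets). Grey points did not pass the test, red points (Coro1a, Cnn2 and Flna) did, and black bars are list medians, such as +0.41 for the receptors.

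Of 12 tested p53 target genes, 9 were higher, with a median of +0.40 (camera adjusted p = 0.0044, and adjusted p = 0.60 with an estimated correlation). None passed over all probes; adjusted over the list alone 1 rose, the pro-apoptotic gene Bbc3, from 6.53 ± 0.05 to 7.39 ± 0.01 (SD, n = 3, adjusted p = 0.080 over all probes). Zmat3 (+0.63) and Fas (+0.38) came next. The camera call ended without wild-type replicate 1 (median +0.47, adjusted p = 0.0504). All 8 tested interferon response genes were higher by mean, with a median of +0.26 (camera adjusted p = 0.042, and adjusted p = 0.60 with an estimated correlation) and none past the test over all probes or adjusted over the list alone; Rsad2 (+0.58), Irf7 (+0.33) and Ddx58 (+0.28) had the smallest p. That call ended without wild-type replicate 1 (+0.32), wild-type replicate 2 (+0.25) or knockout replicate 1 (+0.17), and the median was +0.16 without wild-type replicate 3. For a shift one way, fry passed none of the receptor, integrin, granule, p53 and interferon lists (adjusted p = 0.19 for each), and for either direction it passed p53 targets (0.0039), integrins (0.014) and granule genes (0.039) but not receptors (0.053) or interferon genes (0.18). Without wild-type replicates 2 and 3, the arrays rich in Mpo and Cpa3, the medians were +0.20 for p53 targets and +0.25 for interferon genes, and camera still set both lists apart (adjusted p = 0.0065 and 0.047).

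Genes of megakaryocyte regulation and the cell cycle showed no shift that passed. Of 15 megakaryocyte transcription factors none passed over all probes or adjusted over the list alone (median +0.04, camera adjusted p = 0.79), with Mrtfa, an SRF cofactor, at +0.86 (SE 0.27), Hes1 at +0.86 (SE 0.30) and Ldb1 at -0.23. Of 18 tubulin, spectrin and membrane genes none passed either way (median +0.13, adjusted p = 0.27), with Tuba1a at -0.63, Tubb6 at -0.53 and Tubb4b at +0.42. Of 19 mitosis genes none passed either way (median -0.15, adjusted p = 0.19), with Kif23, a kinesin of cytokinesis, at -0.59, Nusap1 at -0.31 and Ube2c at -0.59; camera called the list without knockout replicate 3 (median -0.21, adjusted p = 0.027), and its median was -0.01 without knockout replicate 1. The small medians of the transcription factor, replication and heat shock lists changed sign with single arrays left out, over ranges of -0.04 to 0.04, -0.07 to 0.10 and -0.05 to 0.13. Of 22 DNA replication genes none passed either way (median -0.00, adjusted p = 0.79), with Ccne2 at -0.70, Ccnd3 at +0.60 and E2f1 at +0.43. Of 13 heat shock and unfolded protein response genes none passed either way (median +0.08, adjusted p = 0.58), with Hsp90b1 at +0.63, Trib3 at -0.69 and Pdia6 at +0.70.

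Markers of other blood cells differed among arrays of the same group, the mast cell list mainly among the wild-type arrays and granulocyte markers within both groups. The granulocyte marker mean ran from 7.40 to 10.69 in the wild-type and from 7.33 to 10.77 in the knockout. Cpa3 and Mcpt8, proteases of mast cells and basophils, lay at 12.64 and 11.45 in wild-type replicate 2 and at 12.88 and 11.97 in replicate 3, but at 6.62 and 5.49 in replicate 1 and between 6.10 and 8.21 in the knockout. The granulocyte genes Mpo and Elane, which are not among the 69 named genes, were high on the same 2 arrays and on knockout replicate 1 (13.07 and 11.25). They lay between 5.84 and 8.98 on the other 3. Of 15 granulocyte members on the array, 8 were at least 1 higher in wild-type replicates 2 and 3 than in replicate 1. Camp (7.68, 8.03 and 7.88 in wild-type replicates 1 to 3) and Ngp (6.33, 6.44 and 6.48) differed little among them. Neither the 2 tested mast cell members (median -3.09, camera adjusted p = 0.19) nor the 9 tested granulocyte members (median -0.65, adjusted p = 0.58) passed over all probes or adjusted over the list alone. The filter removed 14 of 16 mast cell and 6 of 15 granulocyte members on the array. With no filter the medians were -0.12 and -0.14, and the stricter filter gave +0.03 for granulocyte members. The granulocyte members with the smallest p were Camp (+0.80), Prtn3 (-1.62) and Fcnb (-0.65). Camera called the mast cell list without wild-type replicate 1 (median -5.15, against -1.96 without wild-type replicate 3) and the granulocyte list without knockout replicate 1 (median -1.33, against -0.27 without knockout replicate 2).

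**Figure D3:**
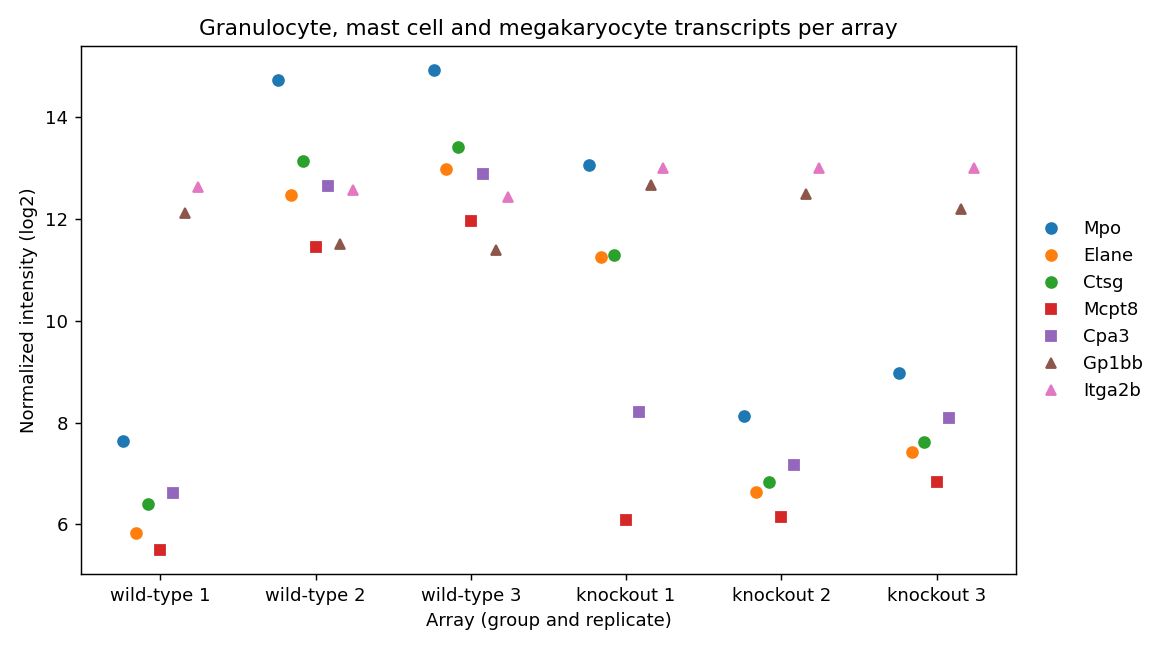
Normalized intensity (log2, vertical axis) of granulocyte genes (circles), mast cell and basophil genes (squares) and megakaryocyte genes (triangles) in each array (horizontal axis). Mpo lies at 14.74 and 14.93 in wild-type replicates 2 and 3, 13.07 in knockout replicate 1 and 7.64 in wild-type replicate 1, while Itga2b stays between 12.43 and 13.01.

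Kit, Klf1, Bcl11a and Aqp1 were highest on the arrays where the mast cell and basophil genes were high. Kit, the stem cell factor receptor used in the sort, lay at 11.53 and 11.67 in wild-type replicates 2 and 3 and between 9.27 and 10.52 elsewhere. Klf1, an erythroid transcription factor, lay at 8.64 and 9.20 there and between 6.28 and 7.05 elsewhere. Of 7 stem and progenitor genes none passed over all probes or adjusted over the list alone (median -0.65, camera adjusted p = 0.19), and the median was -0.31 without wild-type replicate 3 and +0.16 without wild-type replicates 2 and 3, with Bcl11a at -1.52 and Hoxa7 at -0.73. The stem list's median was -0.07 with no filter (18 members) or with the mast cell marker mean, and -0.02 with the stricter filter. Of 8 erythroid genes none passed either way (median -0.05, or +0.05 without knockout replicate 3, adjusted p = 0.58), with Aqp1 at -1.61 and Epor at +0.24. Of 3 lymphocyte markers none passed over all probes; adjusted over the list alone Cd79b fell (-0.80, SE 0.21), with Ebf1 at +0.41 and Nkg7 at -0.93 (median -0.80, adjusted p = 0.58). The lymphocyte median was -0.36 without wild-type replicate 2, -0.32 without wild-type replicate 3 and +0.71 without both, and it was +0.06 with no filter (17 members) and +0.64 with the mast cell marker mean. Of 4 monocyte and macrophage markers none passed either way (median +0.39, adjusted p = 0.21), with Cd74 at +0.82, Mrc1 at +0.54 and Lyz2 at +0.23, and camera called the list without knockout replicate 2 (median +0.57), whereas the median was +0.18 without knockout replicate 1 and +0.07 with no filter (17 members). With the mast cell marker mean camera also called it (median +0.64, adjusted p = 0.019, against 0.0074 to 0.77 over its alternatives). Tek at -0.05 was the one stromal or endothelial marker tested. The Y-linked genes Eif2s3y and Kdm5d lay at 4.98 and 5.38 in wild-type replicate 1, not well above background, and between 10.81 and 11.51 and between 7.08 and 7.96 on the other 5 arrays (median +1.62, adjusted p = 0.24). Camera called this list without wild-type replicate 3 (median +2.33), and with the mast cell marker mean (median +3.57), and its median was +0.32 without wild-type replicate 1 and +0.80 with no filter.

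By whole-array correlation across the tested probes, a description with no test in which genes are not independent replicates, wild-type replicates 2 and 3 resembled each other (r = 0.988), as did knockout replicates 2 and 3 (r = 0.988). Wild-type replicate 1 was closer to knockout replicates 2 and 3 (r = 0.985 and 0.986) than to the other wild-type arrays (r = 0.968 and 0.960). The first principal component, with 53.8% of the variance, set wild-type replicates 2 and 3 apart from the rest. The second, with 20.7%, set knockout replicate 1 (+29.4) apart, with wild-type replicate 1 at its other end (-17.2). Without wild-type replicate 1, 22 further named genes passed the test, among them Mcpt8, Cpa3, Aqp1, Klf1, Bcl11a and Prtn3, all lower in the knockout, and Tbxa2r, Gp1bb, Tgfb1, F5, Junb and Bbc3, all higher.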

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

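The models with marker means and the fit without wild-type replicates 2 and 3 were chosen after seeing the data; the estimated correlation in camera was part of the plan and was counted as an alternative later. Srf passed under all 20 alternatives run on it, with log2 differences from -4.94 to -3.32 on the authors' scale, and Coro1a under 19 of 20, missing the threshold in the unmoderated test (adjusted p 2.5e-06 to 0.054 over the alternatives). The cause of the changes below was not tested, except where fewer arrays, fewer probes or a narrower filter is itself the change. Against 15 probes (13 lower, 2 higher), no filter and the stricter filter each called 9 (8 lower, 1 higher), the unmoderated test 4 (3 lower, 1 higher), and the authors' values 10 (8 lower). Array weights called 1955 (853 lower, 1102 higher), with a weight of 5.91 for wild-type replicate 2 against 0.320 for wild-type replicate 1. The granulocyte marker mean in the model gave 19 calls, 5 of them higher. Leaving out 1 array gave 7 to 639 calls, 6 to 288 lower and 1 to 351 higher; the highest values came without wild-type replicate 1, and that fit kept all 15. Without wild-type replicates 2 and 3, where the spread comes from the knockout arrays and the lone wild-type array is assumed to vary like them, 14 probes passed, 10 of them among the 15.

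With the replicate number as a block 6 probes passed (5 lower, 1 higher), and the stem and progenitor list was called (-0.65, adjusted p 0.046, against 0.046 to 0.89 over its alternatives). The labels do not say whether the numbers pair the samples. Same-numbered arrays deviated from their group means with correlations of -0.27, -0.13 and -0.09, which shows no likeness by number. The differing cell markers of the arrays within a group could hide one.

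Against 5 gene lists called, the stricter filter called 3, the mast cell marker mean in the model 9, the fit without wild-type replicates 2 and 3 also 9, and camera with an estimated correlation 0. That correlation ended the calls at unchanged medians of 0.41 for receptors, 0.45 for integrins, 0.34 for granule genes, 0.40 for p53 targets and 0.26 for interferon genes. Without wild-type replicates 2 and 3 the calls for integrins (0.11) and granule genes (0.062) ended, and the mast cell (1.03) and granulocyte markers (1.14) turned positive with a call. The SRF-MRTF (-0.14), immediate early (0.19), monocyte (0.78) and sex-linked lists (4.23) gained a call there, and the uncalled stem (0.16) and lymphocyte medians (0.71) turned positive and the actin median (-0.07) negative. The mast cell marker mean, high in wild-type replicates 2 and 3 alone, gained the same 4 calls (-0.13, 0.07, 0.64 and 3.57). The granulocyte marker mean gained mitosis (-0.16) and monocyte markers (0.43). Array weights gained calls for mast cell (-4.79) and granulocyte markers (-1.21). The stricter filter ended the p53 call (0.35), whose median ran from 0.28 to 0.51 with 1 array left out. The interferon call also ended with normexp at offset 50 (0.18), no background correction (0.15), percentile scaling (0.24), the authors' values (0.12), the stricter filter (0.24), eBayes with trend (0.26) and array weights (0.31), and its median ran from 0.16 to 0.37 with 1 array left out.

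Of the 68 named genes beside Srf, none turned its direction with a call on either side under these alternatives. Array weights called 43 more of them and the unmoderated test lost 10. Set tests were not run with the unmoderated test, and a slide block was not run because the files name no slide. Signal over background limits 4 of the falls: Ptges3l, Irak2, Dcaf12 and the unnamed probe were undetected in the knockout, and the authors' values gave -0.74, -0.59 and -0.34 for the named ones. Snx24, dim in the knockout, went from -1.16 to -0.66 with offset 50, -0.49 without background correction and -0.31 with the authors' values, each without a call, and passed under 4 of 19 alternatives.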

Other observations

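The tests below were chosen after the result they bear on was seen, except the splits of the arrays; the model with the mast cell marker mean was also added after seeing the data, but its bound for the receptors was set before its result was seen. Some probes took a high or a low value on single arrays without regard to genotype; they were picked after their values were seen. Psmc1, a proteasome subunit, lay at log2 10.99, 10.51 and 10.88 in wild-type replicates 1 and 3 and knockout replicate 3, and at 5.12, 6.20 and 6.66 on the other 3 arrays. Ing4 lay at 6.38 in knockout replicate 1 and between 9.27 and 9.82 on the other 5 arrays. Ndufb10, a subunit of respiratory complex I, lay at 10.61 in wild-type replicate 1 and between 7.24 and 7.83 elsewhere. Fbxw5 lay at 11.31 in wild-type replicate 3, 8.25 in wild-type replicate 1 and between 5.73 and 6.42 elsewhere.

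Prg2 and Ly6c1, on none of the lists, were high where the mast cell or granulocyte markers were, and were picked after their values were seen. Prg2, which encodes eosinophil major basic protein, lay at 11.30 and 11.57 in wild-type replicates 2 and 3 and between 6.32 and 8.13 elsewhere. Ly6c1 lay at 12.06 and 12.46 there, 10.93 in knockout replicate 1 and between 6.25 and 8.32 on the other 3 arrays. Ngp, a granulocyte list member picked in the same way, did not follow Mpo and stood out in knockout replicate 1 alone, at 8.78 against 6.19 to 6.48. S100a8, S100a9, Camp, Lcn2 and Ltf, of the same list, were also highest in knockout replicate 1. S100a8 lay at 13.23 there, against 10.87 and 11.20 in wild-type replicates 2 and 3. Mpo, Elane, Ctsg and Prtn3 were instead higher in wild-type replicates 2 and 3. The granulocyte profile of knockout replicate 1 therefore differed from theirs.

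Over all members on the array, tested or not, 8 of 15 granulocyte and 7 of 16 mast cell and basophil markers were at least 1 higher in both wild-type replicates 2 and 3 than in replicate 1. The latter included the untested Prss34 (10.49 and 10.86), Hdc (8.95 and 9.05), Ms4a2 (7.86 and 7.94), Fcer1a (7.64 and 7.82) and Cd200r3 (7.44 and 7.75), which failed the filter because it asks for detection on all 3 arrays of a group. The mast cell genes Mcpt1, Mcpt2, Mcpt4, Cma1, Tpsb2 and Tpsab1 were undetected on all 6 arrays. The granulocyte genes Ltf, Mmp8, Mmp9 and Itgam were undetected on both wild-type replicates 2 and 3. Of the tested members, 8 of 9 granulocyte and 1 of 2 mast cell ones were also detected in wild-type replicate 1.

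The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division called 15 probes and the highest of the others 4, so 1 of the 10 gave as many. That next division set wild-type replicates 2 and 3 with knockout replicate 1, the arrays rich in granulocyte transcripts, against the rest, and had 1554 probes at an unadjusted p under 0.05 against 1290 for the real one, which points to a structure of the samples beside genotype. For the gene lists the real division called 5 and the highest of the others 6, so 3 of the 10 gave as many.

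Wild-type replicate 1 resembled the knockout more than its own group. A wrong genotype label is argued against, since its Srf lay 4.75 on the log2 scale above the highest knockout array. The sex of the animals, which its lack of Eif2s3y signal brings up, is argued against as the source of the split: the knockout arrays all have that signal, yet over the 300 probes apart by at least 1 between replicate 1 and both other wild-type arrays, the knockout mean lay at a median share of 0.157 of the gap (quartiles -0.0132 and 0.368), where 1 would be the level of replicates 2 and 3. A candidate explanation for the transcripts higher in wild-type replicates 2 and 3 is RNA of granulocytes, mast cells or basophils, or of their progenitors. Such cells, or cells that gave rise to them during the 3 days of culture, would have had to pass the depletion and the sort. Which of these applies was not tested. Of the 11 tested markers, 8, led by Mpo at 14.74 and 14.93, were at least 1 higher in both arrays. Over all members on the array this held for 8 of 15 granulocyte and 7 of 16 mast cell and basophil ones. Which of these cells remains open, and of the latter list Mcpt1, Mcpt2, Mcpt4, Cma1, Tpsb2 and Tpsab1 were undetected on all 6 arrays. RNA of such cells would lower the transcripts that they lack. Whether it accounts for those lower there could not be decided. The 204 probes at least 1 lower in wild-type replicate 2 than in replicate 1 were looked up in wild-type replicate 3. There they lay a median of 0.99 below knockout replicates 2 and 3, against an upper quartile of 0.70 for the platelet receptors. But these probes were picked for a large fall, and wild-type replicates 2 and 3 were much alike (r = 0.988). It was also not checked that the other cells lack the receptors. Culture stage or handling were not tested.

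The platelet receptors' median of +0.41 in the knockout may reflect dilution of wild-type RNA by those other cells, or a change with genotype. With the granulocyte marker mean in the model the median was 0.40, which argues against a whole source that follows that mean. It does not bear on RNA of other cells confined to wild-type replicates 2 and 3. The granulocyte marker mean was 10.77 in knockout replicate 1, against 10.49 and 10.69 in wild-type replicates 2 and 3. Mpo was lower in knockout replicate 1 (13.07, against 14.74 and 14.93). With the mast cell marker mean in the model the receptors' median was 0.26, still past camera's threshold at the preset correlation. That mean, of Cpa3 and Mcpt8, was 12.05 and 12.42 in wild-type replicates 2 and 3 and between 6.06 and 7.46 on the other arrays. What remained therefore rests mostly on wild-type replicate 1 against the knockout. The model cannot tell a part linked to genotype from a trait of that array. The estimated correlation between the receptors, 0.43, is what takes the list's adjusted p to 0.60. Genotype stays open as the source of what remains.

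The rise of Cxcl5 did not follow granulocyte markers: its difference was 3.32 with their mean in the model, and wild-type replicates 2 and 3, rich in Mpo, had Cxcl5 at 7.19 and 7.14. Cxcl5 lies next to Ppbp and Pf4 in the gene order of GRCm38.p6, and a hypothesis is that a Pf4-Cre transgene built from a long genomic segment could carry extra copies of its neighbours. The 3 other tested genes of this neighbourhood had a median difference of -0.15 (Pf4 +0.33, Ppbp -0.82, Afp -0.15). Cxcl3 and Cxcl2, on the other side of Pf4, were each detected on 1 knockout array and no wild-type array. Extra copies cannot be told apart from an effect of Srf loss, since the labels do not say whether the wild-type cells carried the transgene, too few neighbours were measured, and Pf4 and Ppbp lie near the top of the intensity scale.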
